A study of Nostoc sp. PCC 7120 = FACHB-418 with 4 samples.

How the data were processed

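Total RNA of the filamentous, nitrogen-fixing cyanobacterium Anabaena (Nostoc) sp. PCC 7120 was measured on 4 one-colour custom Agilent arrays, 2 of uninfected cultures and 2 of cultures treated with cyanophage A1. Per the labels' protocols, RNA was extracted with hot phenol, freed of DNA with DNase, and 2 µg were coupled directly to Cy3 without reverse transcription, so each probe read 1 strand. Each array held 62976 spots. Of these, 61537 were not controls and carried 55217 distinct probes for 19836 named features: 6079 genes with a median of 3 probes, 9372 intergenic regions read on both strands, 4379 windows of 147 nt, and 6 named small RNAs, which had 20 probes on 6200 spots.

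The deposited scanner files held intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity per spot was background-subtracted, corrected for spatial trends by subtraction and multiplication, and replaced by a small surrogate value where it did not exceed background, per the file headers. It was not normalized between arrays. The headers gave 1 slide and 1 scan for all arrays, so neither could be fitted as a batch. The authors' series table held log2 values with no stated scale or centring; limma is named, with no role, in the submitters' processing notes. Set against the scanner values of the same arrays, its columns followed log2 of the median spot intensity (Pearson correlation over spots 0.999 to 1.000, slope 0.956 to 1.03), and the median of each was 7.72. Their percentiles differed between arrays by at most 0.0067, as after quantile normalization. The background correction behind the series table stayed unknown, and it was used as an alternative only.

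Outlier spots and control spots were left out. A probe counted as well above background on an array where at least 0.5 of its spots carried that flag. Between 9.74% and 10.4% of non-control spots per array were well above background, and the 75th percentile over all spots fell on surrogate values (77.9 and 20.3 intensity units on the uninfected arrays, 33.0 and 17.2 on the infected arrays). Each array's log2 processed intensity was therefore set relative to its 75th percentile over the 2842 probes well above background on all 4 arrays, in place of the percentile over all non-control spots that had been planned; the planned version was run as an alternative. Spots of a probe were averaged, then probes of a feature. A feature was tested where at least 1 of its probes was well above background on both arrays of a group. That left 991 genes (16.3%), 1375 intergenic regions (14.7%), 238 windows (5.44%) and 4 small RNAs. Dim probes stayed in a gene's mean: in 187 of the 991 tested genes (18.9%) every probe was well above background on both arrays of a group, and in 580 of the 984 tested genes with several probes (58.9%) the probes differed in the sign of the change. Where no probe of a feature was well above background on any array of a group, its fold is given as a lower bound: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The folds of changed genes with only some probes dim in uninfected cultures are bounds of the same kind, with each uninfected probe value raised to that lowest signal. No spot carried the saturation flag.

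Group differences (infected minus uninfected, log2) were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 4 arrays, two-sided, without a block, with Benjamini-Hochberg adjustment over the tested genes and, apart from them, over the tested non-coding features. The threshold was an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 13 of 29 lists with at least 5 tested members, and again with an estimated correlation and with fry. The lists were fixed before the data were examined. The tables used here held no product descriptions, so the lists' text patterns were replaced by patterns on gene symbols, written before any group difference was computed, beside the lists' 146 locus tags, of which 8 had no match on the array. Lists for high light and photoprotection, phage-related host genes and tRNA genes had no member that could be found this way, and the list of small RNAs was read from the array's own names. Plasmids were compared with the chromosome by Fisher's exact test on the counts of changed genes.

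Gene names on the array were matched by coordinates and strand to the RefSeq gene table of assembly ASM970v1, whose chromosome is the version the array names. Start and end were identical for 4799 genes, 811 shared the strand and stop, and 469 stayed unmatched and are given by position. All coordinates are 1-based on that assembly. The rule for named genes, fixed with the lists, took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 changed members per list or otherwise the 2 members with the largest difference, 5 non-coding rises and 5 falls, and, with fewer than 10 changed genes, the 10 genes with the smallest p. Names for locus tags without a symbol in the table (sigG, sigE, pecA, pecC, rbcL, rbcS) are the usual ones for these loci. No feature was named for the phage, so its transcripts were not analysed here.

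The test was checked on simulated arrays drawn from the means and variances of the 991 tested genes, with 200 genes changed, in 20 runs of the 2 against 2 comparison. Of genes changed by 1 on the log2 scale 77.6% were found, of those changed by 2 99.5%, of those changed by 3 99.9% and of those changed by 4 all (100%); 4.05% of all calls were false. A list of genes shifted by -0.7 was called in 14 of 20 runs. The simulation used variances already moderated across genes, drew genes independently and changed 200 genes, against 5 called in the data. More changed genes loosen the adjusted threshold, so the shares found cannot be carried over to these data. In the data, 5 of the 48 genes with a log2 difference beyond 1 passed.

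The alternatives were other scalings (array median, quantile, the percentile over gene probes alone), normexp background correction with an offset of 50 followed by the percentile or by quantile normalization, the authors' log2 values, other filters, the median or the brightest probe of a gene, a trended or robust prior, the replicate number as a block, other thresholds and each array left out. Because the mean spot intensity is not a column of the files, normexp was run on the median intensity and median background. The percentile over detected probes replaced the planned one after the detection rates were seen, so the planned one became an alternative only then. Also chosen after seeing the data was the removal of 23.1% of spots that lay in areas where the multiplicative correction exceeded 1.25 on any array. That correction reached 5.72 on the array of uninfected replicate 1, over a dim area at its left edge, against at most 1.31 on the infected arrays and 1.00 on that of uninfected replicate 2. The number of arrays, 2 per group, limited the precision of every value.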

Results

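Early transcript levels were compared between Anabaena sp. PCC 7120 cultures kept with and without cyanophage A1. Each culture had been divided, 1 portion received the phage at a multiplicity of infection of 2, and both were harvested after 1 h at 30 °C; the whole procedure was done again for a replicate. There were 2 uninfected and 2 infected samples, each on an array of its own. Between 5991 and 6426 spots per array were well above background. Over the 991 tested genes the infected arrays correlated with each other at 0.980 and the uninfected arrays at 0.920, while correlations across the groups lay between 0.901 and 0.933 (Pearson, across genes, which are not independent replicates). The SD of the log2 difference between replicates was 0.62 for the uninfected pair and 0.31 for the infected pair. A probe of the small RNA NC-11, with 490 to 594 usable copies per array, had an SD over its copies of 0.28 on the array of uninfected replicate 1 and of 0.11 to 0.14 on the others (log2 processed intensity).

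The comparison asks which host genes differ 1 h after phage addition. The largest change was in nrdJ (all4035, chromosome 4860196 to 4863714, minus strand), the gene of a ribonucleotide reductase, the enzyme that makes deoxyribonucleotides for DNA synthesis. Its log2 signal, relative to the array's 75th percentile of detected probes, was -5.17 ± 0.14 (SD, n = 2) in uninfected and -0.50 ± 0.24 (SD, n = 2) in infected cultures, a measured difference of 4.67 (SE 0.21, limma adjusted p = 0.0042). All 3 probes were well above background on both infected arrays, but 2 were not on either uninfected array and the other on only 1 of the 2. The rise is therefore given as at least 10.73-fold. In log2 that bound was 3.42 (SE 0.26, from the spread of the arrays). Without strongly corrected spots it was 7.28-fold, over 2 of the 3 probes. Genes for 2 sigma factors, the subunits that direct RNA polymerase to promoters, also passed the threshold with higher signal. The sigma factor gene sigG (alr3280, chromosome 3954895 to 3955551, plus strand) rose at least 5.46-fold, with measured means of -4.27 ± 0.03 and -1.25 ± 0.07 (SD, n = 2; limma adjusted p = 0.0072). Of its 3 probes, 1 was well above background on both uninfected arrays, 1 on neither and the other on only 1 of the 2. The sigma factor gene sigE (alr4249, 5097964 to 5099136, plus strand) was not well above background in uninfected cultures and was at least 1.12-fold higher in infected ones, with measured means of -6.14 ± 0.17 and -3.93 ± 0.18 (SD, n = 2; limma adjusted p = 0.026). Only 1 of its 3 probes was well above background on both infected arrays. Its bound was 0.17 in log2 (SE 0.14, from the spread of the arrays), while its p used measured signals of 3 probes that were dim in uninfected cultures.

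In all, 5 of 991 tested genes rose and 0 fell (limma, adjusted p under 0.05), and 113 had an unadjusted p under 0.05, 35 of them with a higher and 78 with a lower mean after infection. The remaining 2 changed genes lay next to other features that were higher. One was asl4034 (4859718 to 4859936, minus strand), the gene downstream of nrdJ, which was not well above background in uninfected cultures and was at least 2.11-fold higher in infected ones (means -6.004 ± 0.188 and -3.022 ± 0.304, SD, n = 2; limma adjusted p = 0.015). Its p, too, used measured signals of 3 probes that were dim in uninfected cultures. The other was an unnamed gene at 780208 to 780402 on the plus strand of the chromosome, which rose at least 3.25-fold, with measured means of -4.02 ± 0.04 and -1.56 ± 0.07 (SD, n = 2; limma adjusted p = 0.013) and 1 of its 3 probes not well above background in uninfected cultures. For 430 of the tested genes (43.4%) the infected and uninfected arrays did not overlap. A share of 33.3% would follow if every order of the 4 arrays were equally likely. Genes share array-wide deviations, so the excess cannot be read as an effect of infection. Some features well above background on no array, such as alr4032 and all4037, also did not overlap. All 5 changed genes were higher in every alternative that tested them, but none kept its call when the median of a gene's probes replaced their mean, when dim genes were kept in the test or when either infected array was left out (0 genes each). Leaving out uninfected replicate 1 or 2 gave 120 and 237 changed genes, the lone uninfected array then being assumed to vary like the infected pair, and scaling to the 75th percentile of all spots gave 5 higher and 1 lower.

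**Figure D1:**
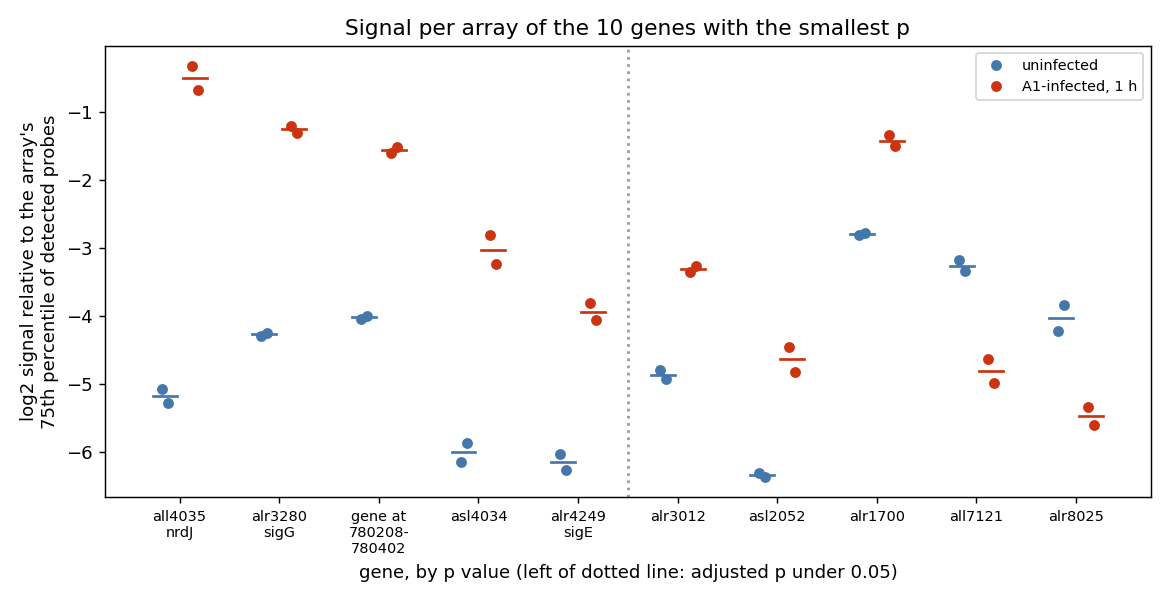
Points are single arrays (blue, uninfected; red, infected for 1 h) and short bars are means of 2 arrays; the y axis is log2 signal relative to the array's 75th percentile of detected probes, for the 10 genes with the smallest p on the x axis. The 5 genes left of the dotted line passed an adjusted p under 0.05, and nrdJ had an infected mean of -0.50, while its uninfected points lay below the lowest signal well above background.

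The next genes by p did not pass the threshold. The log2 difference was 1.56 (SE 0.18) for alr3012 and 1.37 (SE 0.18) for alr1700, with limma adjusted p of 0.061 and 0.085. For asl2052 no probe was well above background on an uninfected array and no fold is given (measured means -6.33 and -4.63, limma adjusted p = 0.071). The difference was -1.55 (SE 0.21, limma adjusted p = 0.089) for all7121 on plasmid alpha. On plasmid gamma, alr8025 was not well above background after infection and was at least 1.05-fold lower (means -4.03 and -5.47, limma adjusted p = 0.16).

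Around nrdJ, the higher signal was confined among tested features of the map to the minus strand between 4859582 and 4863714. The region between asl4034 and nrdJ (4859937 to 4860195, minus strand) was not well above background in uninfected cultures and was at least 3.56-fold higher in infected ones (means -5.59 ± 0.16 and -2.27 ± 0.39, SD, n = 2; limma adjusted p = 0.036 over non-coding features). The region past asl4034 (4859582 to 4859717) had a difference of 1.64 (SE 0.29) that did not pass (limma adjusted p = 0.41). The minus strand just upstream of nrdJ (4863715 to 4864108) was not well above background on any array. On the other locus, the neighbours of the unnamed gene had differences of the same sign without passing the threshold: 0.99 (SE 0.17) for alr0668, 1.13 (SE 0.28) for alr0669, 1.75 (SE 0.33) for the unnamed gene at 780750 to 781547 and 1.10 (SE 0.23) for alr0672, all on the plus strand, with limma adjusted p from 0.19 to 0.26. The minus strand next to them was also at higher values without passing, 1.09 (SE 0.35) for all0667 and 0.76 (SE 0.18) for the region at 776993 to 777619 (limma adjusted p = 0.33 and 0.69).

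**Figure D2:**
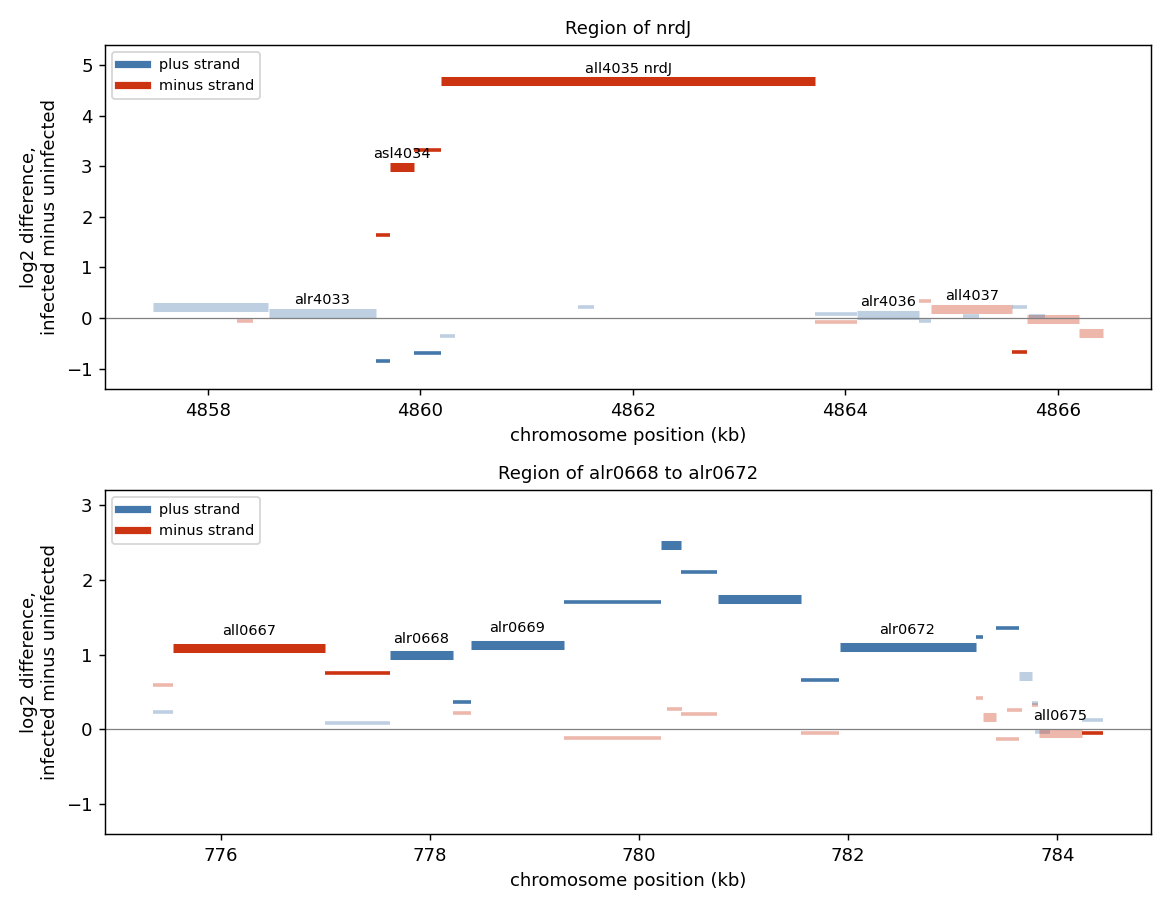
Horizontal bars show the log2 difference (infected minus uninfected, y axis) of each gene (thick) and each intergenic region or window (thin) against chromosome position in kb, on the plus strand (blue) and the minus strand (red); pale bars were not tested. Where uninfected signal was dim the bar is a measured difference, not an exact one. The upper map shows nrdJ at a measured 4.67 with its minus-strand neighbours, and the lower map the unnamed gene at 780208 to 780402 at a measured 2.46 among plus-strand features with smaller differences.

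Of the 13 gene lists with at least 5 tested genes, 4 passed camera, 1 upward and 3 downward. None of the 4 calls held with an estimated correlation (camera adjusted p = 0.56 for the sigma factors and for CO2 fixation, 0.66 for the phycobilisome and for ATP synthase) or with fry (adjusted p = 0.053, 0.065, 0.18 and 0.34, in that order of lists). With an estimated correlation and 4 arrays, camera had 2 residual degrees of freedom, so a list could hardly pass and those losses say little. The sigma factor list (5 tested) was higher (median log2 difference 0.45, camera adjusted p = 0.0031): 2 members rose, 0 fell and 3 did not pass, and 2 were changed when adjusted over the list alone. Its members that did not pass included rpoD (all5263), the principal sigma factor gene, at -0.52 (SE 0.27). The phycobilisome list, genes of the light-harvesting antenna, was lower (20 tested, median -0.50, camera adjusted p = 0.00080). None of its 20 members passed on its own, 18 lay below 0 and 6 of these had an unadjusted p under 0.05. The largest differences were those of pecA (alr0524, 616972 to 617460), -1.23 (SE 0.24), and pecC (alr0525, 617607 to 618443), -0.99 (SE 0.21). The 3 probes of pecA ranged from -3.01 to -0.06, and only 1 was well above background in each group. Those of pecC ranged from -1.32 to -0.77, and all 3 were. Of these genes, pecA is for phycoerythrocyanin, a pigment protein at the ends of the antenna rods. The gene cpcA (alr0529), for the more abundant phycocyanin, was at 0.28 (SE 0.26). The ATP synthase list was lower (9 tested, all 9 below 0, none past the threshold, median -0.68, camera adjusted p = 0.011), with atpD (all5039) at -0.84 (SE 0.24) and all0004 at -0.85 (SE 0.34). The list of CO2 fixation and concentration was lower (8 tested, all 8 below 0, none past the threshold, median -0.46, camera adjusted p = 0.0091). Its largest differences were those of all0864, -0.72 (SE 0.21), and alr0318, -0.60 (SE 0.21), and the Rubisco genes rbcL (alr1524) and rbcS (alr1526) were at -0.48 (SE 0.21) and -0.43 (SE 0.18). In the 3 lower lists 0 genes were changed when adjusted over the list alone. Without uninfected replicate 2, the 3 lower lists lost their calls (camera adjusted p = 0.18 for the phycobilisome, 0.68 for ATP synthase and 0.31 for CO2 fixation), with medians of -0.41, -0.28 and -0.47.

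**Figure D3:**
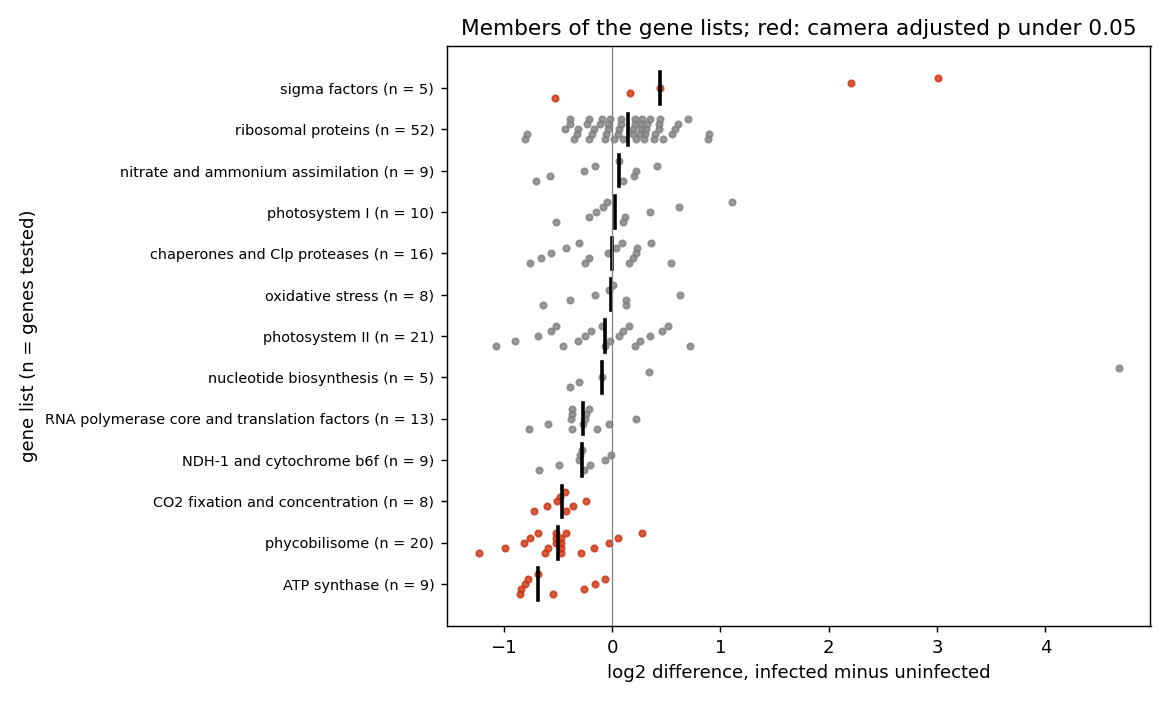
Each point is a tested gene, placed by its log2 difference (infected minus uninfected, x axis) in its list (y axis), and the black bar is the list's median; red lists passed camera at an adjusted p under 0.05. ATP synthase has the lowest median, -0.68, and the sigma factors the highest, 0.45.

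The other 9 tested lists did not pass camera. For ribosomal proteins (52 tested) the median was 0.15 (camera adjusted p = 0.079), with rpsN (all3969) at 0.89 (SE 0.41) and rpmJ (5040545 to 5040658) at 0.89 (SE 0.53). Nucleotide biosynthesis (5 tested, camera adjusted p = 0.25) held nrdJ, its 1 changed gene over all genes and over the list alone, while the median of the list was -0.09 and its mean 0.85. Photosystem I (10 tested, median 0.03) and photosystem II (21 tested, median -0.07) had no changed gene; all0329 was at 1.11 (SE 0.62) and psaK (asr4775) at 0.61 (SE 0.65) in the first, psbF (4644274 to 4644411) at -1.07 (SE 0.24) and psbQ (all1355) at least 1.20-fold lower in the second, since it was not well above background after infection (means -3.86 and -4.75, limma adjusted p = 0.34). The medians were -0.28 for NDH-1 and cytochrome b6f (9 tested), with nuoK (alr0226) at -0.68 (SE 0.23) and petN (5113924 to 5114013) at -0.49 (SE 0.29), and -0.26 for RNA polymerase core and translation factors (13 tested), with efp (all5058) at -0.77 (SE 0.23) and infC (all4623) at -0.59 (SE 0.40). Camera gave both an adjusted p of 0.16. For chaperones and Clp proteases (16 tested, median -0.0027), oxidative stress (8 tested, median -0.0094, mean -0.04, camera direction up) and nitrate and ammonium assimilation (9 tested, median 0.06, mean -0.08, camera direction up) the camera adjusted p was 0.95. In these, the largest differences were those of clpX (alr3684), -0.76 (SE 0.27), ftsH3 (alr1261), -0.65 (SE 0.31), alr2938, -0.64 (SE 0.30), trxB (all0737), 0.63 (SE 0.23), ureA (alr3667), -0.71 (SE 0.23), and asl2329, -0.57 (SE 0.44). No member of these lists other than nrdJ was changed, also when adjusted over each list alone.

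Most genes found for the lists nearest to phage defence and to development were too dim to test. Members were found only by symbol or listed locus tag, and 872 of 6079 array genes had a symbol. The list sizes below therefore count genes found this way, not all genes of a class on the array. Of 16 CRISPR-Cas genes and 2 toxin-antitoxin genes found, 0 were tested, and of 50 genes of heterocysts and nitrogen fixation 1, hetZ (alr0099, 0.13, SE 0.23). DNA replication, repair and recombination had 3 tested genes of 47, among them recA (all3272, -0.65, SE 0.38) and uvrC (alr2728, 0.09, SE 0.20). The 7 restriction-modification genes had 1, dndE (alr4922, 0.06, SE 0.21), the 15 transposase genes 1, tnpB (all7245, -0.28, SE 0.25), which is uncertain because such genes have near-identical copies, and the 24 surface polysaccharide genes 2, hpsL (all4442, -0.38, SE 0.27) and lpxA (alr2272, 0.29, SE 0.18). Glycogen and the oxidative pentose phosphate pathway had 3 of 10, with glgP (all2806) at -0.47 (SE 0.18) and glgA (alr1879) at -0.16 (SE 0.20). Phosphate acquisition had 3 of 26, with pstS (all4575) at -0.25 (SE 0.26) and phoU (all4501) at 0.11 (SE 0.19). The iron acquisition list had 1 of 11, sufC (alr2493, 0.18, SE 0.20). That gene entered by symbol and is for iron-sulfur cluster assembly, so no iron uptake gene of the list was tested. Two-component and Ser/Thr kinases had 1 of 13 (rpaB, all3822, 0.07, SE 0.18). None of these passed limma's threshold, and in each list 0 were changed when adjusted over the list alone.

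Among 1617 tested non-coding and antisense features, 2 rose and 1 fell (limma, adjusted p under 0.05). An unadjusted p under 0.05 was reached by 71, a share no larger than chance alone would give. All 3 changed features were well above background on no array of 1 group, so their p used measured signals that were dim there. Besides the region beside nrdJ, the region at 6413062 to 6413771 on the chromosome's minus strand, next to all5371, was at least 1.62-fold higher in infected cultures (means -5.63 ± 0.08 and -3.41 ± 0.01, SD, n = 2; limma adjusted p = 0.036). The region at 857970 to 858038 on the minus strand, between all0736 and the thioredoxin reductase gene trxB (all0737) and read by 1 probe, was at least 1.22-fold lower (means -3.84 ± 0.03 and -6.02 ± 0.05, SD, n = 2; limma adjusted p = 0.036). Of 238 tested antisense and other windows, 0 passed and 12 had an unadjusted p under 0.05 (limma). With the replicate number as a block, 1 of the 3 kept its call, the region beside nrdJ. The count of 3 was 0 with quantile normalization, with normexp and quantile normalization and with the authors' values. It was 39 without uninfected replicate 1, 158 without uninfected replicate 2 and 0 without either infected array.

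None of the 4 tested small RNAs passed the threshold. NsrR1 was at -2.72 ± 0.03 and -2.49 ± 0.03 (SD, n = 2; difference 0.24, SE 0.18, limma adjusted p = 0.93), NsiR2 at -4.43 ± 0.24 and -4.42 ± 0.12 (difference 0.01, SE 0.21), NC-11 at a difference of -0.18 (SE 0.19) and NC-27 at -0.04 (SE 0.19). NC-7 and NsiR3 were not well above background on any array.

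By replicon, the median log2 difference was -0.08 over 906 chromosomal genes and -0.06 over 68 genes of plasmid alpha. Plasmids beta, gamma, delta and epsilon had 5, 9, 2 and 1 tested genes. All 5 changed genes were chromosomal. Fisher's exact test of each plasmid's share against the chromosome's (two-sided, adjusted p = 1 for each of 5 plasmids) had too few changed genes to tell a plasmid with 0 from the chromosome; without uninfected replicate 1, 1 plasmid differed. At an unadjusted p under 0.05 (limma), plasmid alpha had 7 genes with a lower and 1 with a higher mean among its 68. The chromosome had 69 with a lower and 33 with a higher mean among its 906, a similar share of genes in all.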

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

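The percentile over all spots had been planned as the scaling and became an alternative after the detection rates were seen; removing strongly corrected spots was chosen after seeing the data. The measured log2 differences of the 5 changed genes stayed above 0 in all alternatives that tested them, from 2.21 to 4.88 for nrdJ, 1.38 to 3.38 for sigG and 0.76 to 2.73 for sigE, the lowest under the authors' values. With quantile normalization sigG lost its call (limma adjusted p = 0.052). With the authors' values sigE, asl4034 and the gene at 780208 to 780402 lost theirs (limma adjusted p = 0.063 each). Changed genes numbered 22 (21 higher, 1 lower) with normexp and the percentile, which moved the median of all tested genes by 0.23, 2 (both higher) with the authors' values and with features well above background on all 4 arrays (fewer genes tested), 0 of 6079 without a filter (314 at an unadjusted p under 0.05) and 0 with the median of a gene's probes (108), 10 (4 lower) with the brightest probe, and 9 at an adjusted p under 0.1; 1 gene was lower with the percentile over all spots. Leaving out each array gave 0 to 237 changed genes, 0 to 72 higher, 0 to 165 lower, 0 to 158 non-coding features, 2 to 6 lists and 0 to 1 plasmids. Non-coding features numbered 0 with quantile normalization, normexp and quantile, the authors' values, no filter, all 4 arrays above background or the median probe, 11 with normexp and the percentile, 1 with the brightest probe and 6 with the percentile over all spots. The cause was not tested. Samples share replicate numbers, but the labels do not tie a number to a shared culture: deviations of same-numbered samples correlated at -0.087 (-0.21 with normexp and quantile, -0.24 with the authors' values), and with the replicate block there were 6 changed genes, 1 of them lower, and 1 non-coding feature, the region beside nrdJ. Lists called numbered 2 with the brightest probe, and 0 with an estimated correlation, with fry or from symbols alone.

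Adjusted p of ATP synthase was 0.055 with quantile normalization, 0.066 with the median and 0.081 with the brightest probe, 0.66 with an estimated correlation, 0.34 with fry, 0.064 from symbols alone and 2.34e-05 to 0.678 without 1 array. For CO2 fixation it was 0.13 with the brightest probe, 0.076 with the percentile over all spots, 0.56 with an estimated correlation, 0.065 with fry and 0.0039 to 0.307 without 1 array. For the phycobilisome it was 0.66 with an estimated correlation, 0.18 with fry, 0.78 from symbols alone and 2.34e-05 to 0.183 without 1 array. For the sigma factors it was 0.19 without a filter, 0.56 with an estimated correlation and 0.053 with fry. The medians of these 4 lists kept their sign under each scaling and background alternative, but that of the sigma factors was 0.06 with normexp and quantile and 0.05 with the authors' values, and that of ATP synthase -0.07 with normexp and the percentile and -0.21 with the authors' values. Ribosomal proteins passed upward with normexp and quantile (0.026), the authors' values (0.014) and all 4 arrays above background (0.039), nucleotide biosynthesis upward with the percentile over all spots (0.00063) and normexp and the percentile (0.0055), and RNA polymerase and translation factors (0.00012), photosystem II (0.010) and NDH-1 and cytochrome b6f (0.010) downward without a filter.

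Some uncalled results changed sign. For nitrate assimilation the adjusted p was then 0.999 (array median), 0.59 (normexp and percentile), 0.084 (no filter), 0.82 (brightest probe), 0.99 (replicate block), 0.97 (percentile over all spots), 0.90 (fry) and 0.0302 to 0.989 without 1 array. For chaperones it was 0.94 (quantile), 0.91 (normexp and quantile), 0.74 (authors' values), 0.31 (brightest probe), 0.99 (replicate block), 0.54 (corrected spots left out), 0.35 (locus tags alone), 0.96 (symbols alone), and with or without a change of sign 0.739 to 0.978 without 1 array. For photosystem II it was 0.91 (normexp and quantile), 0.74 (authors' values), 0.36 (brightest probe), 0.85 (corrected spots left out) and 0.080 (locus tags alone). For oxidative stress it was 0.92 (normexp and quantile), 0.83 (normexp and percentile), 0.997 (authors' values), 0.69 (no filter) and 0.90 (fry). It was 0.59 (normexp and percentile) and 0.37 (no filter) for photosystem I, 0.32 (no filter) and 0.207 (without uninfected replicate 1, median -0.14) for ribosomal proteins, 0.66 (no filter) for nucleotide biosynthesis and 0.678 (without uninfected replicate 2) for RNA polymerase and translation factors. Calls were gained in the main direction for ribosomal proteins without uninfected replicate 2 (5.47e-06, median 0.28) and without infected replicate 2 (0.038), in a range of 5.47e-06 to 0.209 without 1 array, and for RNA polymerase and translation factors without uninfected replicate 1 (0.00123).

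With normexp and quantile and with the authors' values the log2 differences of dndE (-0.041, -0.019), sufC (-0.16, -0.12), phoU (-0.16, -0.12) and rpaB (-0.041, -0.030) were below 0; with normexp and the percentile those of nuoK (0.032), efp (0.0021), ftsH3 (0.12), recA (0.13), tnpB (0.044), hpsL (0.23) and pstS (0.16) were above 0. With the median probe dndE was at -0.46 and hetZ at -0.37, with the brightest probe sufC at -0.089 and psaK at -0.12, and without corrected spots pstS at 0.00904 and psaK at -0.16. Without 1 array the ranges that crossed 0 were -0.11 to 0.23 for dndE, -0.0031 to 0.22 for phoU, -0.54 to 0.030 for pstS, -0.11 to 0.38 for hetZ, -0.38 to 1.61 for psaK and -0.031 to 0.21 for uvrC. Wide ranges above 0 were 0.16 to 2.05 for all0329, 0.30 to 1.49 for rpsN and 0.20 to 1.57 for rpmJ. Over all alternatives, 738 values of named genes kept direction and side of the threshold, 25 lost and 44 gained a call and 27 changed sign. Spots left out as saturated and a slide or scan block were not run, since no spot was saturated and all arrays shared 1 slide and scan. Signal over background left 16.3% of genes to test.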

Other observations

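The tests on phage RNA, on nrdJ without corrected spots, on uninfected replicate 2, on neighbours with genes left out and on neighbours between uninfected replicates were chosen after the result was seen. The predictions of the others were written before their results, though the removal of strongly corrected spots was itself chosen after seeing the data. Neighbouring genes tended to move alike. Over 266 pairs of tested neighbours on the same strand, log2 differences correlated at 0.529 (Pearson; Spearman 0.38), against 0.12 (Spearman 0.19) over 70 neighbours on opposite strands; across genes, which are not independent. The gap between strands had a one-sided permutation p of 0.028 for Pearson and 0.066 for Spearman, so a shared transcript as the source of the joint change may hold but stays open. With all genes of the 2 loci named above left out, the correlations were 0.32 and 0.05 (permutation p = 0.04 for Pearson and 0.081 for Spearman); with only the 5 changed genes left out they were 0.35 and 0.12 (0.07 and 0.098). The same contrast appeared with no infection in it: between uninfected replicates 1 and 2 the correlation was 0.45 for same-strand and -0.06 for opposite-strand neighbours, so joint movement of neighbours is not specific to phage addition.

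Antisense RNA was set against the sense gene in 21 pairs of tested windows and genes. Spearman's rho was -0.076 (two-sided permutation p = 0.74), which met the bound set in advance against opposite movement. That bound was wrong for so few pairs, since only a rho beyond 0.44 in size would have reached p = 0.05, so opposite movement may occur and stays open.

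The rise of the nrdJ segment was weighed against 3 technical explanations. Phage RNA bound by the probes of the segment stays open, since neither bound set for it was met and no phage sequence was used here. The 3 nrdJ probes had measured differences of 4.47 to 4.98. None was under 1, which would have spoken against it, but they did not span more than 2, which was set as its sign. Labelled DNA or RNA of both strands would raise the opposite strand too, which was at -0.68 (SE 0.43, from the spread of the arrays) there, though dim after infection, and at -0.85 (SE 0.36) past asl4034, where it was well above background on all arrays. Spatial correction on the array of uninfected replicate 1 would shrink the difference once strongly corrected spots were left out. The measured difference of nrdJ, over its 2 remaining probes, was then 4.74, and its call held. The difference was at least 2.86 (SE 0.22 from the spread of the arrays) with dim uninfected values raised to the lowest signal well above background. This argues against the correction for the whole rise; for part of its size it stays open, since the 3 set to exclude that was not reached. A higher level of a host transcript over nrdJ and asl4034 after infection remains as a hypothesis beside phage RNA, and rests on 2 arrays per group.

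For the lower phycobilisome, ATP synthase and CO2 fixation lists, the spatial correction was argued against: without strongly corrected spots 3 of the 3 lists kept more than 0.5 of their median difference relative to all tested genes (-0.43, -0.75 and -0.48, in that order). A bias that depends on signal was also argued against, since the medians lay at or below percentile 0.08 of 10000 random lists matched on mean level. High values on the array of uninfected replicate 2 alone could not be excluded: without it, 2 of the 3 lists kept that share, the relative medians being -0.27, -0.14 and -0.34, and ATP synthase did not. For the phycobilisome and ATP synthase lists, joint variation of the members also stays open, since their estimated correlations were 0.26 and 0.36. Neither passed with them, but that test had 2 residual degrees of freedom and could hardly have passed a list. The CO2 fixation list had an estimated correlation of -0.11, so its lost call is no sign of joint variation. In all 3 lists infection itself may be the source of the difference.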
